A study of Homo sapiens with 6 samples.

How the data were processed

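RNA from OCI-LY8 cells grown in serum-containing medium was sequenced in 6 libraries, 3 labelled sgNTC control and 3 labelled with a guide against SETD1B. Per the labels, total RNA was purified on columns and libraries were made with a stranded poly(A) mRNA kit. Per the submitters' processing notes, CASAVA 1.8, Trimmomatic, HISAT2, featureCounts and DESeq2 were used with the hg38 build. The annotation, the strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here. Genes that overlap or have near-identical copies are therefore uncertain, and 47 of the 12877 genes with a mean count of 10 or more carried the same 6 counts as another gene.

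The authors deposited a table of whole-number read counts per gene for the 6 libraries, with 26485 gene symbols, of which 18486 had a count in at least 1 library. The deposited table holds raw counts, and it holds 0 per-sample columns that were not used. Total counts were 34453249, 28726108 and 30259783 for control replicates 1, 2 and 3 and 30970194, 29230551 and 31758876 for knockout replicates 1, 2 and 3. At these depths 3 counts, the upper limit that a count of 0 allows, stand for 0.0871 to 0.104 CPM, and such limits cover counting error only. The second deposited table holds log2 values of 12029 genes. Each value was the log2 of the deposited count times 1 factor per library (0.949 to 1.14), with no pseudocount, and entries with a count of 0 had no value. How these genes were selected is not given in the sources used here. The table has no fold changes or p-values, so the planned comparison with the authors' own calls was not made.

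Groups and replicate numbers came from the sample titles. No 2 libraries agreed within sampling noise, with a chi-square per degree of freedom from 1.71 upward for replicate pairs. The main test was edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, a quasi-likelihood fit with robust dispersion and group as the term, and Benjamini-Hochberg adjustment over 12907 genes at a threshold of 0.05. The SE is the absolute log2 fold change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. Before the data were examined, 36 gene lists were written down for B-cell states, apoptosis, signalling, growth, metabolism, chromatin and other cell types. The 34 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 34 lists. The mitochondrially encoded genes had 0 members in the table and the epithelial list had 3 tested members, so neither was tested. A list count "adjusted over the list alone" uses Benjamini-Hochberg within that list.

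The genes named were fixed by rule before the data were examined. They are SETD1B, SETD1A and KMT2D, the 7 highest and 7 lowest fold changes among changed genes with a mean of at least 5 CPM and groups that did not overlap (immunoglobulin and T-cell receptor segments left out), up to 3 changed members with at least 1 CPM of each list that passed camera or had 5 or more changed members, and all tested members of both BCL2 family lists. Genes named after their values were seen are marked as such, and 1 gene that the rule selects is not reported here.

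Alternatives planned before the data were examined were RLE scaling, library size only, TMM without immunoglobulin, ribosomal protein and mitochondrially encoded genes, no filter on low counts, a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, other thresholds (adjusted p under 0.01, at least 2-fold, glmTreat against 1.5-fold), and for lists an estimated correlation and fry. A correction for GC content (a smooth trend per library used as an offset) and limma on the deposited log2 values were added after the data were seen. Positions, GC content and transcript length came from GENCODE 29 on the same build; 23899 symbols matched directly, 715 through another symbol and 1871 did not match. GC content was known for 96.7% of the tested genes.

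The fit was tested on simulated data for this comparison with 200 changed genes among 12816. The simulated genes varied independently and held no GC bias, and a smaller share changed than the 15.0% called in the real data. In these data the fit recovered 56.1% of genes planted at a log2 change of 0.5, 86.6% at 1 and 100% at 2, and 7.95% of all its calls were false. Recovery in the real data may differ.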

Results

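RNA sequencing read counts per gene were available for 6 libraries of OCI-LY8, a human B-cell lymphoma line of germinal centre type. In 3 libraries the cells carried a non-targeting guide RNA (sgNTC control), and in 3 they carried a guide RNA against SETD1B (SETD1B knockout). SETD1B is a histone methyltransferase of the family that also holds SETD1A and KMT2D. The comparison asked what SETD1B loss changes in a lymphoma line that the series' design text describes as KMT2D mutant. That text names another line, OCI-LY19, while the labels of all 6 samples name OCI-LY8, and the sample labels were followed. Between 28726108 and 34453249 reads per library were assigned to genes, and 12907 genes had enough counts to be tested. The labels do not say that the 3 replicates of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical. All 3 libraries of a group carry the same guide name. An effect of SETD1B loss therefore cannot be told apart from any other difference between the control and knockout cells, including copy number. Values below are normalised counts (CPM) ± SD with n = 3 per group, and log2 fold changes are knockout minus control from edgeR's quasi-likelihood test.

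The SETD1B transcript itself (chromosome 12, 121804180 to 121832584, hg38) was not lower in the knockout libraries. It stood at 56.1 ± 3.25 CPM in the controls and 77.6 ± 19.5 CPM in the knockouts, where replicates 1, 2 and 3 held 87.4, 90.2 and 55.1 CPM. The log2 fold change of 0.47 (SE 0.18) missed the threshold (edgeR adjusted p = 0.14). It passed without knockout replicate 3 (log2 0.66, edgeR adjusted p = 8.1e-07), after a correction for GC content (log2 0.52, edgeR adjusted p = 5.2e-05) and with DESeq2 (log2 0.48, adjusted p = 0.035). SETD1B is rich in GC (64.7%), and the knockout libraries deviated with GC content, as described below. The value without replicate 3 may therefore include a GC-linked difference. Small insertions or deletions need not lower a transcript's count, so these values do not check the edit, and "knockout" here names the label. The relatives SETD1A (81.3 ± 3.8 against 82.7 ± 18 CPM) and KMT2D (267 ± 7.83 against 266 ± 53.5 CPM) had log2 fold changes of 0.02 and -0.00, and edgeR adjusted p values of 0.95 and 0.99. Without knockout replicate 3 both passed upward (log2 0.19 and 0.15, edgeR adjusted p = 0.0074 and 0.0035), whereas after the GC correction neither did (edgeR adjusted p = 0.23 and 0.55).

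The largest loss among the genes named by rule was that of JCHAIN, the joining chain of secreted IgM and IgA, which fell 87.8-fold, from 610 ± 15.0 to 6.94 ± 0.616 CPM (log2 -6.46, SE 0.08, edgeR adjusted p = 6.3e-08). BTBD3 fell 68.9-fold from 42.6 CPM and PDIA2, a protein disulphide isomerase, fell 61.8-fold from 12.4 CPM. RGS1, a regulator of G-protein signalling, fell 8.59-fold, and the non-coding genes LINC01225, LINC01226 and LOC101927412 fell 8.93-fold to 9.90-fold. LINC01225 and LINC01226 overlap on chromosome 1, so the split of reads between them is uncertain. Among the increases, ALDH1A1, a retinaldehyde dehydrogenase, rose 8.81-fold, from 1.40 ± 0.453 to 12.2 ± 1.22 CPM (log2 3.14, SE 0.22, edgeR adjusted p = 2.3e-04). AFF2 rose 3.72-fold to 180 CPM, the neutral sphingomyelinase gene SMPD3 2.80-fold, S1PR2 2.58-fold, TTC28 2.45-fold and HPGD, a prostaglandin-degrading enzyme, 2.35-fold. SNORD28, a small nucleolar RNA whose reads cannot be separated from those of its host gene, rose 2.26-fold.

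Across the transcriptome, 1941 genes (15.0%) changed at an edgeR adjusted p under 0.05, of which 737 were higher and 1204 lower in the knockouts. At least 2-fold changes were seen for 90 of the higher and 313 of the lower genes. In all 1941 genes the 3 knockout values lay on the same side of the 3 control values, a separation that 37.7% of all tested genes showed and chance gives to 10%. Knockout replicate 3 stood apart from the other 2 knockout libraries, with a value of -30.1 on the second principal component (24.6% of the variance) against 15.0 and 20.8. Without it, edgeR called 5795 genes, 2817 higher and 2978 lower, including 1940 of the 1941 with the same direction. Leaving out a control library gave 779 to 841 and leaving out knockout replicate 1 gave 1102. Knockout replicates 1 and 2 also differed from the controls by GC content. In the 10% of genes highest in GC their median deviations from the mean of all libraries were 0.16 and 0.30, against 0.01 to 0.10 in the controls. Counts without replicate 3, here and for the lists below, may therefore include GC-linked differences.

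**Figure D1:**
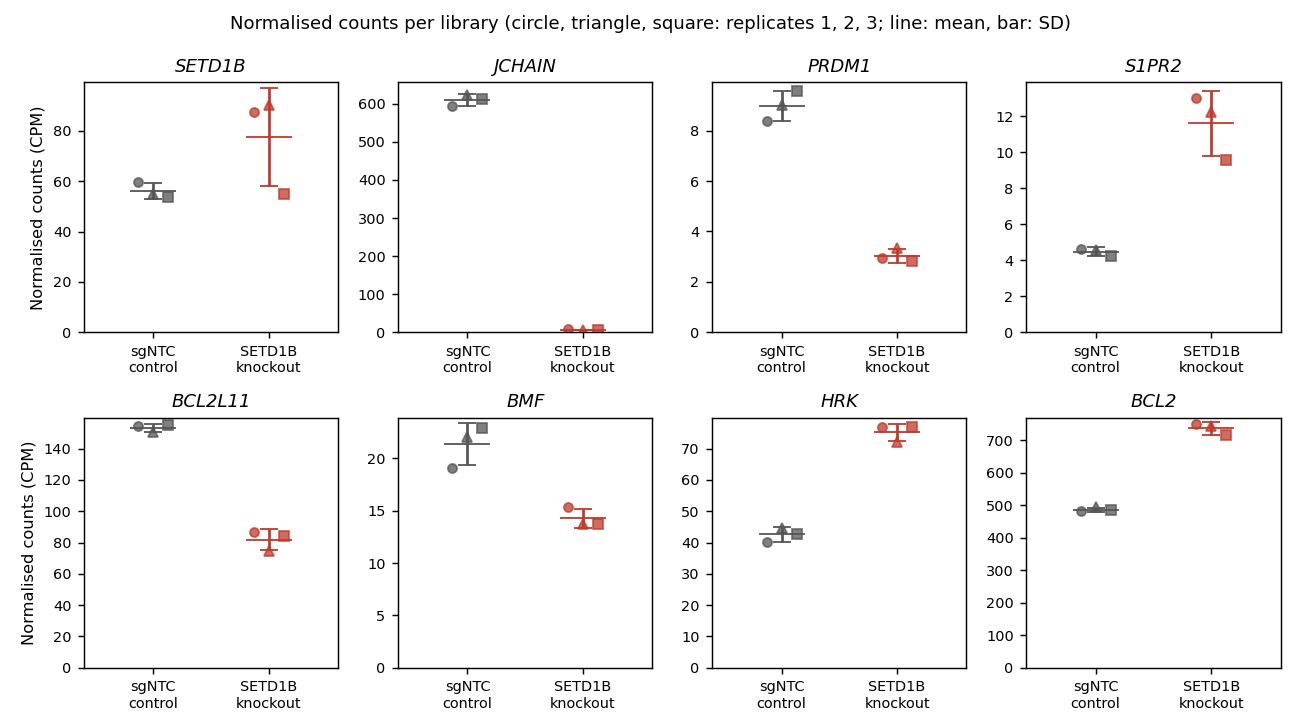
Normalised counts (CPM, linear axes from 0) of 8 genes in the 3 sgNTC control and 3 SETD1B knockout libraries, where symbols are single libraries, horizontal lines the group means and bars 1 SD. SETD1B was lower in knockout replicate 3 (55.1 CPM) than in replicates 1 and 2 (87.4 and 90.2 CPM), whereas JCHAIN, PRDM1, BCL2L11 and BMF were lower and S1PR2, HRK and BCL2 higher in every knockout library than in every control.

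More plasma cell genes fell than rose. Of 19 tested members of the plasma cell differentiation list, 10 fell, 1 rose and 8 did not pass (10 fell and 2 rose when adjusted over the list alone). Beside JCHAIN, PRDM1, the transcription factor that drives plasma cell formation, fell from 8.98 ± 0.590 to 3.03 ± 0.266 CPM (log2 -1.57, SE 0.11, edgeR adjusted p = 3.0e-04). TNFRSF17, the plasma cell receptor for BAFF and APRIL, fell 2.29-fold. CD27, the member that rose (log2 0.96), was named after its value was seen. The list was lower than the other genes (camera adjusted p = 9.4e-04, but adjusted p = 0.36 with an estimated correlation). Without knockout replicate 3, 10 members fell and 3 rose.

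More genes rose than fell in the germinal centre list. In that list 10 of 27 tested members rose, 2 fell and 15 did not pass (11 rose and 4 fell when adjusted over the list alone). S1PR2, a receptor that confines B cells to germinal centres, rose from 4.48 ± 0.229 to 11.6 ± 1.81 CPM, NEIL1 from 125 ± 3.97 to 251 ± 55.7 CPM and ELL3 from 38.4 ± 1.16 to 76.3 ± 3.69 CPM. BCL6, the factor that maintains the germinal centre state and was named after its value was seen, rose with a log2 fold change of 0.59. TCL1A (log2 -0.58) and LMO2 (log2 -0.44), also named afterwards, fell. The list was higher than the other genes (camera adjusted p = 0.0022, adjusted p = 0.36 with an estimated correlation), and 16 members rose and 6 fell without knockout replicate 3. Among 23 light-zone and CD40-activated genes 4 fell and 1 rose (4 and 2 adjusted over the list alone), and the list's median and mean differed in sign (0.12 and -0.03, camera adjusted p = 0.60). Without knockout replicate 3 the balance turned, with 8 that rose and 5 that fell. GPR183, a migration receptor that draws B cells out of germinal centres, fell 2.59-fold, BATF 2.42-fold and SLAMF1 1.90-fold.

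B-cell surface and identity genes split. Of 21 tested, 6 rose, 5 fell and 10 did not pass (8 rose and 5 fell when adjusted over the list alone). TNFRSF13B, the receptor TACI, fell 3.74-fold from 15.9 ± 0.488 CPM, BANK1 fell 1.90-fold and MS4A1, which encodes CD20, fell from 441 ± 8.83 to 259 ± 29.9 CPM. The list as a whole missed the threshold (camera adjusted p = 0.17) and passed it upward without knockout replicate 3 (camera adjusted p = 0.021), where 14 members rose and 5 fell, and after the GC correction (camera adjusted p = 0.038, 12 rose and 5 fell). In the list of B-cell trafficking and adhesion genes 5 of 23 fell and 3 rose (6 and 3 adjusted over the list alone, camera adjusted p = 0.23; 12 and 6 without knockout replicate 3). CXCR5, the chemokine receptor for B-cell follicles, rose from 32.3 ± 1.27 to 72.4 ± 15.3 CPM, so that CXCR5 and S1PR2 were higher while GPR183 was lower.

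In the BCL2 family, pro-apoptotic members went both ways. Of 10 tested members 3 fell, 1 rose and 6 did not pass, with the same numbers adjusted over the list alone. Without control replicate 2, only 1 fell and 1 rose. BCL2L11, which encodes BIM, fell from 153 ± 2.37 to 81.8 ± 6.55 CPM (log2 -0.91, SE 0.07, edgeR adjusted p = 3.3e-04). BMF fell 1.49-fold and PMAIP1, which encodes NOXA, fell 1.27-fold, while HRK rose 1.77-fold. Log2 fold changes of the 6 others were 0.22 for BBC3, 0.09 for BIK, 0.05 for BAX, -0.01 for BAD, -0.06 for BID and -0.23 for BAK1, with edgeR adjusted p from 0.38 to 0.99. The list as a whole missed the threshold (camera adjusted p = 0.48), and without knockout replicate 3 it held 3 members that rose (HRK, BBC3 and BAX) and 3 that fell. After the GC correction BBC3 and BAX did not pass (edgeR adjusted p = 0.13 and 0.11). There 1 member rose and 4 fell, among them BAK1 (log2 -0.19, edgeR adjusted p = 0.016). Of 5 anti-apoptotic members, BCL2 rose from 487 ± 6.14 to 737 ± 19.1 CPM (log2 0.60, SE 0.05, edgeR adjusted p = 3.8e-04) and MCL1 rose 1.21-fold. BCL2L1 (log2 0.22), BCL2A1 (0.56) and BCL2L2 (-0.20) did not pass (4 members higher and 1 lower passed when adjusted over the list alone), but BCL2L1 passed without knockout replicate 3 (log2 0.30). This list was higher than the other genes (camera adjusted p = 0.035, adjusted p = 0.36 with an estimated correlation), a call that ended without control replicate 1 (camera adjusted p = 0.061), without knockout replicates 1, 2 and 3 in turn (0.060, 0.061 and 0.053) and with no low-count filter (0.12). Among 21 caspase and apoptosome genes 3 fell, led by CASP10 (2.27-fold) and the cytochrome c gene CYCS (1.42-fold), and 2 rose, with the inhibitor BIRC3 1.41-fold higher (5 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.96; 5 and 4 without knockout replicate 3).

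**Figure D2:**
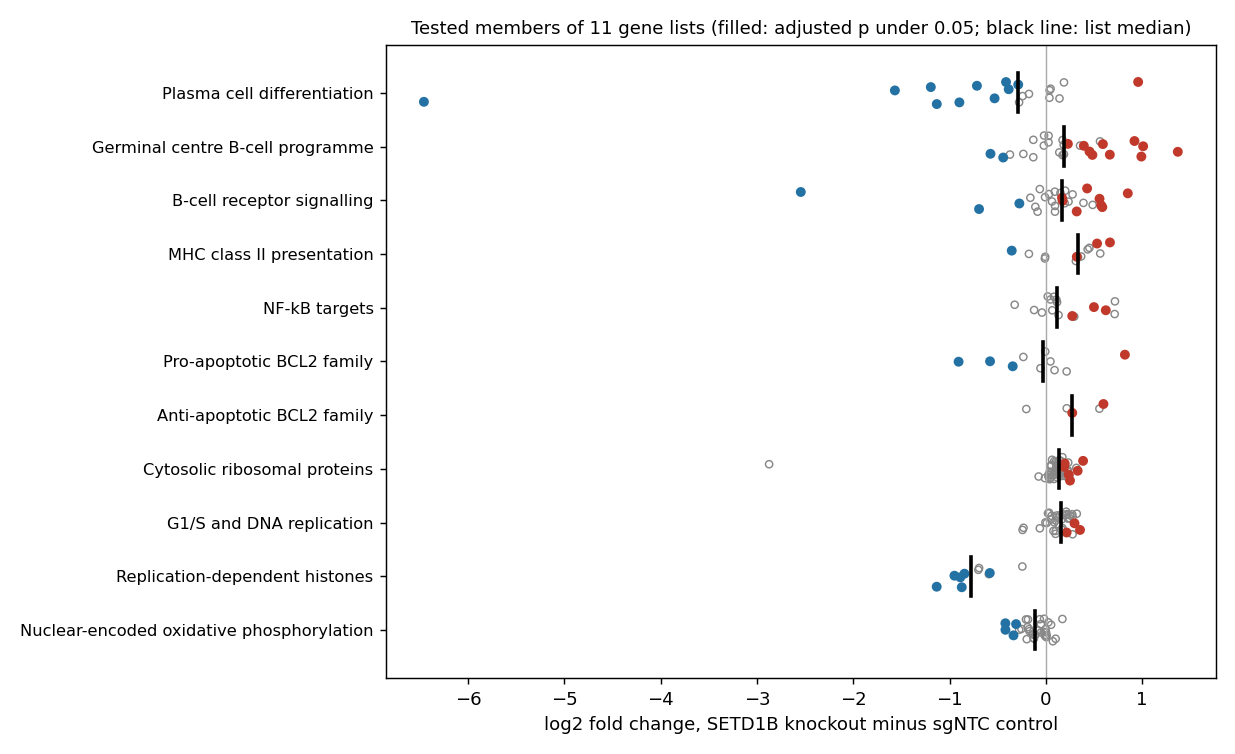
Log2 fold change (knockout minus control, x axis) of each tested member of selected gene lists (y axis), where red and blue points passed an edgeR adjusted p of 0.05 upward and downward, open points did not, and black lines are list medians. The plasma cell list has a median of -0.29 and the histone list, counted in poly(A) libraries, of -0.77, against 0.18 for the germinal centre list.

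B-cell receptor signalling, NF-kB target and MHC class II genes leaned upward. Of 29 receptor signalling genes 8 rose and 3 fell (9 and 4 adjusted over the list alone; 18 and 4 without knockout replicate 3). SH3BP5, an inhibitor of the kinase BTK, rose from 14.8 to 26.6 CPM, while the kinase genes FYN (5.83-fold) and PRKCB (1.62-fold) fell, and the list was higher than the other genes (camera adjusted p = 0.030, adjusted p = 0.36 with an estimated correlation). In the NF-kB target list 3 of 16 rose and 13 did not pass, with the same numbers adjusted over the list alone, and 10 rose without knockout replicate 3. REL rose from 80.3 ± 2.49 to 124 ± 4.57 CPM, BIRC3 1.41-fold and CD83 1.21-fold (camera adjusted p = 0.030, adjusted p = 0.36 with an estimated correlation). MHC class II genes gave 3 higher and 1 lower of 13 (7 and 1 adjusted over the list alone, 8 and 2 without knockout replicate 3). HLA-DRA was 1.59-fold and HLA-DOA 1.45-fold higher and IFI30 1.28-fold lower (camera adjusted p = 0.030 for the list, adjusted p = 0.37 with an estimated correlation). Counts of some genes in the MHC region jumped between replicates, such as the untested HLA-DPA1 (3, 7 and 410 reads in the controls), which limits this list. All 3 calls ended without control replicate 1 (camera adjusted p = 0.054, 0.054 and 0.061 for the receptor, NF-kB and MHC class II lists) and without knockout replicate 2 (0.061, 0.064 and 0.061). The receptor and NF-kB calls also ended without knockout replicate 1 (0.060 and 0.11), and that of the NF-kB list with no low-count filter (0.079). Both of these lists missed the threshold with fry as well (fry adjusted p = 0.069 and 0.066). Among 35 interferon response genes 5 rose and 3 fell (9 and 3 adjusted over the list alone; 12 and 9 without knockout replicate 3), with IFIH1 1.83-fold and EPSTI1 1.62-fold higher and IFI44 1.56-fold lower. The median of this list was -0.06 and its mean 0.03 (camera adjusted p = 0.45).

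Growth and metabolic lists moved in both directions. Of 53 cytosolic ribosomal protein genes 6 rose and 47 did not pass (5 rose when adjusted over the list alone), and 45 rose without knockout replicate 3. RPS27 rose 1.31-fold, RPS20 1.26-fold and RPL30 1.19-fold (camera adjusted p = 3.4e-05, adjusted p = 0.36 with an estimated correlation). In the list for G1/S and DNA replication 3 of 36 rose and 33 did not pass (1 rose when adjusted over the list alone; 16 rose and 3 fell without knockout replicate 3), with GINS3 1.28-fold, the helicase subunit MCM3 1.23-fold and GINS4 1.16-fold higher (camera adjusted p = 0.0022, adjusted p = 0.36 with an estimated correlation). Replication-dependent histone genes gave 6 lower of 10, also when adjusted over the list alone, and 6 lower of 12 without knockout replicate 3. HIST1H2BJ fell from 1.81 ± 0.0861 to 0.823 ± 0.142 CPM, HIST1H2BC 1.93-fold and HIST1H2BD 1.85-fold (camera adjusted p = 1.4e-04, adjusted p = 0.36 with an estimated correlation). The libraries were made with a poly(A) kit, so these counts need not follow histone transcripts without a poly(A) tail. Of 33 nuclear-encoded oxidative phosphorylation genes 4 fell and 29 did not pass, also when adjusted over the list alone, with NDUFA9 and ATP5A1 both 1.34-fold and SDHC 1.26-fold lower, against 18 lower and 5 higher without knockout replicate 3. That list's call (camera adjusted p = 0.044, adjusted p = 0.52 with an estimated correlation) ended under RLE scaling (camera adjusted p = 0.063), with the replicate number as a block (0.069) and without control replicates 1 and 2 or knockout replicates 1 and 2 in turn (0.10, 0.0502, 0.26 and 0.061).

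In lists that missed the camera threshold, single genes still changed. Of 21 glycolysis genes 4 fell and 1 rose, also adjusted over the list alone, with ALDOC 1.64-fold and PGK1 1.38-fold lower and PFKFB4 1.81-fold higher (camera adjusted p = 0.13). Of 19 hypoxia targets 3 fell and 2 rose (4 and 4 adjusted over the list alone), with BHLHE40 2.05-fold and MXI1 1.37-fold lower, a median of 0.02 and a mean of -0.03 (camera adjusted p = 0.99). Of 27 cholesterol synthesis genes 4 fell and 2 rose, also adjusted over the list alone, with ELOVL6 1.67-fold and LSS 1.58-fold lower (camera adjusted p = 0.39). Among 23 p53 targets 4 rose and 3 fell (6 and 3 adjusted over the list alone), with TP53INP1 1.90-fold, POLH 1.42-fold and FAS 1.37-fold higher (camera adjusted p = 0.40). Without knockout replicate 3 more members passed: 8 glycolysis, 7 hypoxia, 13 cholesterol and 4 p53 genes fell, and 4, 5, 4 and 12 rose.

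Markers of other cell types moved in both directions. Of 6 tested myeloid markers 4 fell and 2 did not pass, also adjusted over the list alone, among them ITGAM (7.29 ± 0.843 to 2.39 ± 0.351 CPM), TYROBP (1.99-fold) and CST3 (1.63-fold). The call (camera adjusted p = 0.030, adjusted p = 0.52 with an estimated correlation) ended without control replicates 1 and 2 or knockout replicates 2 and 3 in turn (camera adjusted p = 0.063, 0.076, 0.061 and 0.13) and with no low-count filter (0.30). Of 6 fibroblast and stromal markers 2 rose and 1 fell, also adjusted over the list alone, and 4 rose and 1 fell without knockout replicate 3 (camera adjusted p = 0.035, adjusted p = 0.36 with an estimated correlation). This call ended without control replicate 2 or knockout replicates 1 and 2 in turn (camera adjusted p = 0.0502, 0.098 and 0.061), after the GC correction (0.099) and with no low-count filter (0.48). LUM, which encodes the matrix protein lumican, had 0 counts in the controls and 223 in the knockouts, at least 25.2-fold higher against a floor of 3 counts per control library. DCN, its neighbour on chromosome 12 and named after its value was seen, also rose (1 count against 38). These increases thus come from the same locus. S100A6 fell 1.65-fold. With LUM at that bound the median of the list stayed at 0.42, and its mean was 1.59 in place of 2.36.

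Genes of chromosome 21 were lower almost throughout. Of its 102 tested protein-coding genes 96 had a negative log2 fold change, 63 fell by edgeR, and the median was -0.42 (0.749-fold). Medians of 10000 random sets of 102 genes ran from -0.10 to 0.09. These sets make no allowance for the choice of chromosome 21 as the lowest of all chromosomes. The chromosome medians of the 3 knockout libraries relative to the control mean were -0.37, -0.36 and -0.41. Much of chromosome 18 beyond 40 Mb was lower as well. From 40 to 50 Mb 17 of 18 genes were negative with a median of -0.31, and from 50 to 60 Mb 20 of 21 were, 13 of which fell, with a median of -0.35. The medians were -0.21 from 60 to 70 Mb (8 of 11 negative) and -0.18 from 70 to 80 Mb (13 of 16). Chromosome 20 was lower to a smaller degree in its windows from 0, 10, 20 and 30 Mb. There 38 of 50, 19 of 21, 17 of 19 and 52 of 75 genes were negative, with medians of -0.16, -0.13, -0.25 and -0.14. Among the genes named above, LSS (log2 -0.66) lies on chromosome 21, and ATP5A1 (log2 -0.42), PMAIP1 (log2 -0.34) and BCL2, which rose, lie on chromosome 18 in the windows from 40, 50 and 60 Mb. BTBD3 (log2 -6.11), CST3 (log2 -0.71) and BCL2L1 (log2 0.22, not called) lie on chromosome 20 in the windows from 10, 20 and 30 Mb.

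**Figure D3:**
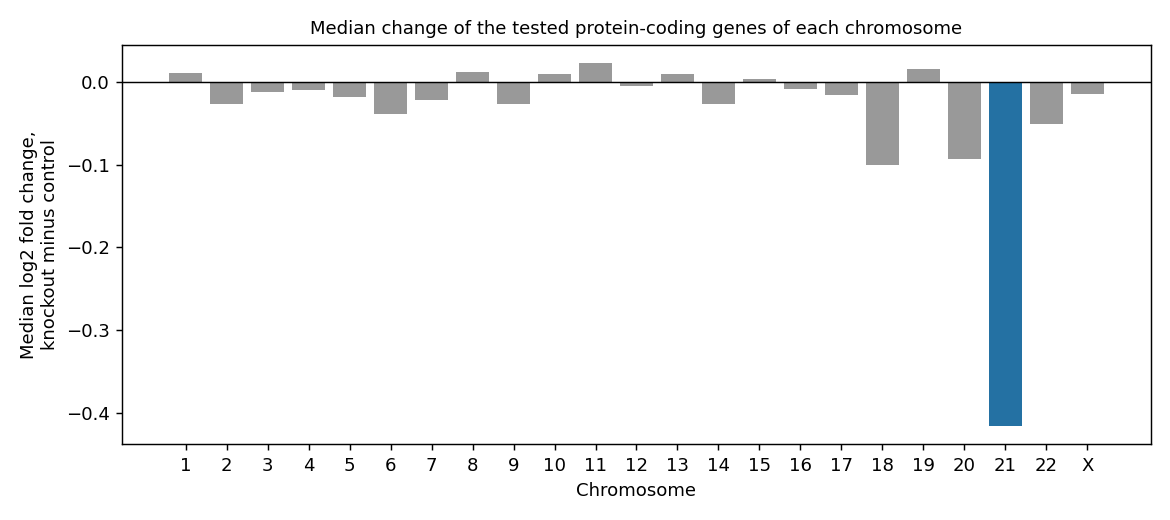
Median log2 fold change (knockout minus control, y axis) of the tested protein-coding genes of each chromosome (x axis), as bars from 0. Chromosome 21 has a median of -0.42, while chromosomes 18 and 20, the next lowest, have -0.10 and -0.09.

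The difference of knockout replicate 3 from the other knockout libraries varied with GC content. Its log2 difference from the mean of the other 2 knockout libraries had a Spearman correlation of -0.784 with transcript GC content across 12476 genes, which are not independent replicates. Among 10 bins of genes ordered by GC content, in the highest the median deviation of replicate 3 from the mean of the 6 libraries was -0.59, against 0.16 and 0.30 for knockout replicates 1 and 2. After a correction for GC content edgeR called 4849 genes, 2309 higher and 2540 lower, and replicate 3 still stood apart on the second principal component (19.6 against -10.6 and -9.11 for knockout replicates 1 and 2).

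**Figure D4:**
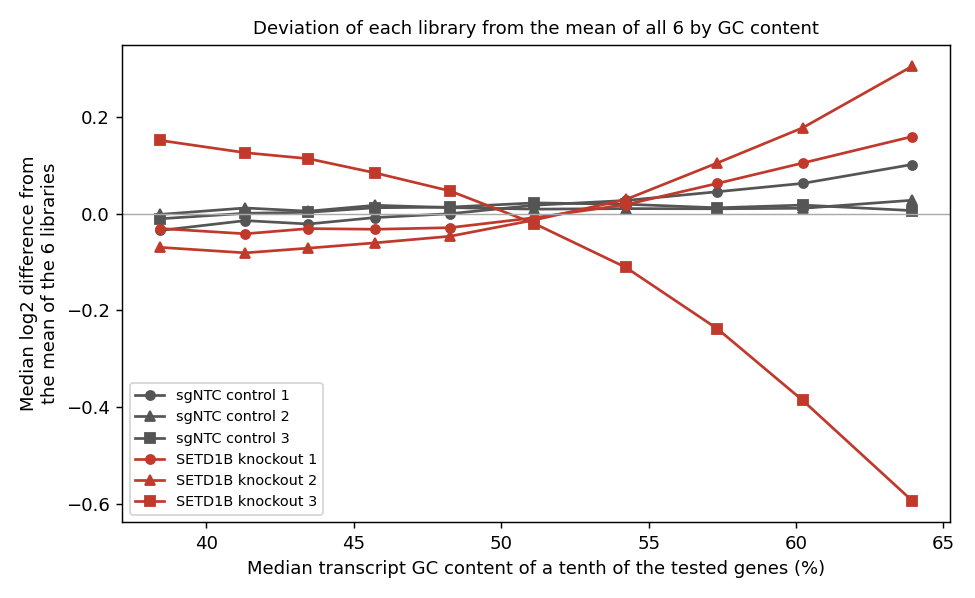
Median log2 deviation of each library from the mean of the 6 libraries (y axis) in 10 bins of the tested genes ordered by transcript GC content (x axis, percent), with lines for single libraries. Knockout replicate 3 runs from 0.15 in the bin of lowest GC content to -0.59 in the highest, opposite to knockout replicates 1 and 2, while the 3 controls lie between -0.03 and 0.10.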

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

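The GC correction and limma on the deposited log2 values were chosen after the data were seen. The count of 1941 genes stayed between 1589 and 1944 under both other scalings, TMM without selected genes, both filters, DESeq2, limma-voom and the deposited log2 values. With the GC correction it was 4849 (2309 higher, 2540 lower; 1926 shared in the same direction), at an adjusted p under 0.01 it was 828 (276 and 552), at 2-fold 403 (90 and 313) and with glmTreat 263 (46 and 217). Leaving out a library gave 779 to 5795 genes, 252 to 2817 higher and 527 to 2978 lower: 841, 779 and 826 without controls 1, 2 and 3, and 1102, 1518 and 5795 without knockouts 1, 2 and 3. Higher genes made up 38.0% of calls, but 48.6% without knockout 3. Numbers shared between groups did not pair the samples (correlations of deviations -0.01, -0.10 and 0.08); with the replicate number as a block 1326 genes were called (450 higher, 876 lower), SETD1B was at 0.44, and 4 pro-apoptotic members and 11 lists passed. SETD1B stayed above 0 and passed with DESeq2 (0.48), the GC correction (0.52) and without knockout 3 (0.66); leaving out a library gave 0.34 to 0.66, and adjusted p over all alternatives ran from 8.1e-07 to 0.34. Pro-apoptotic calls were 2 to 6 when a library was left out (2 without control 2) and 5 with the GC correction (1 higher, 4 lower). Of 12 lists, 0 passed camera with an estimated correlation (2 at an unadjusted p under 0.05). Fry, which tests against no change and not against other genes, called 14 of 34 lists, 10 of them among the 12. Camera called 9 lists with no low-count filter (8 among the 12), 14 with the GC correction (11 among the 12) and 5 to 12 when a library was left out (6 without control 1, 5 without knockout 2). The plasma cell, germinal centre, G1/S, ribosomal protein and histone lists passed with each library left out; the 7 others did not. Of 73 named genes past the threshold, 50 stayed past it with each library left out. The other 23 lost the call in at least 1 of these fits and are not marked by name above. Of the 73, 0 changed sign in any alternative. Uncalled genes near 0 did: SETD1A with limma-voom (log2 -0.00337), and KMT2D and BAD with RLE scaling (0.00855 and 0.00641), DESeq2 (0.0085 and 0.00756) and the GC correction (0.0339 and 0.0159). Leaving out a library moved SETD1A from -0.10 to 0.19, KMT2D from -0.11 to 0.15, BAD from -0.29 to 0.25, BIK from -0.0177 to 0.18, BID from -0.0914 to 0.0132 and BAX from -0.0521 to 0.18. Stricter thresholds lower a count by construction; for the other differences the cause was not tested. In the simulation, which held no GC bias and fewer changed genes than were called here, changes of log2 0.5 were found in 56.1% of cases.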

Other observations

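Which genes are named in this part was decided after their values were seen, as was the test on alternate copies; the other tests were planned before their results were seen. RAG1, a subunit of the V(D)J recombinase, fell from 1734 ± 21 to 498 ± 37.9 CPM (log2 -1.80, SE 0.07, edgeR adjusted p = 1.8e-05), and its neighbour RAG2 fell from 183 ± 6.61 to 121 ± 7.27 CPM (log2 -0.60). The surrogate light chain genes IGLL1 (log2 -2.24) and VPREB1 (log2 -1.09) fell too, whereas VPREB3 was at log2 0.35 with an edgeR adjusted p of 0.24, and passed upward without knockout replicate 3 (log2 0.55, edgeR adjusted p = 3.2e-06) and after the GC correction (log2 0.39, edgeR adjusted p = 0.0062). IKZF2, a relative of the lymphoid factor IKZF1, fell from 426 ± 15.0 to 125 ± 8.05 CPM. Among 5 tested T and NK cell markers, CD4 fell from 50.3 ± 1.64 to 15.3 ± 2.32 CPM and PRF1 from 14.1 ± 0.841 to 3.42 ± 1.19 CPM (camera adjusted p = 0.081 for the list; 3 fell and 2 rose without knockout replicate 3). BACH2, a repressor of PRDM1 and a member of both the germinal centre and the dark-zone list, rose with a log2 fold change of 0.92, PAX5 with 0.66 and FOXO1 with 0.45. In the dark-zone list 4 of 16 members rose and 12 did not pass (camera adjusted p = 0.13), against 6 that rose and 3 that fell without knockout replicate 3.

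Of 22 tested genes for H3K4 methyltransferases and their shared subunits 2 rose, ASH2L (log2 0.43) and KMT2C (log2 0.19) (camera adjusted p = 0.081). The list passed camera upward without knockout replicate 3 (11 rose, camera adjusted p = 0.030) and after the GC correction (8 rose and 1 fell, camera adjusted p = 0.032). Of 5 H3K4 demethylases KDM5B fell (log2 -0.54) and KDM1B rose (log2 0.28; camera adjusted p = 0.97; 2 and 2 without knockout replicate 3). Of 12 genes near SETD1B, BCL7A rose (log2 0.45) and CLIP1 fell (log2 -0.30; camera adjusted p = 0.88), against 4 that rose and 2 that fell without knockout replicate 3. Among 23 Polycomb and DNA methylation genes 3 fell, DNMT3B, TET1 and BMI1, and 1 rose, DNMT1 (camera adjusted p = 0.88). Without knockout replicate 3, 4 fell and 7 rose, whereas after the GC correction 4 fell and 3 rose. Of 12 tumour suppressors linked to KMT2D 3 fell, S1PR1, DUSP1 and ASXL1, and 1 rose, MAP3K8 (camera adjusted p = 0.99). In this list 3 fell and 4 rose without knockout replicate 3, but 3 fell and 1 rose after the GC correction. For 5 further lists camera gave adjusted p values of 0.077 (G2/M and mitosis, 3 of 32 higher; 0.048 after the GC correction, 12 higher and 2 lower), 0.40 (unfolded protein response, 3 of 27 lower), 0.46 (MHC class I presentation, 1 of 13 higher), 0.88 (ribosome biogenesis, 1 of 29 lower) and 0.99 (stress genes, 1 higher and 2 lower of 19). In the same order 10, 8, 5, 7 and 4 members rose and 6, 9, 3, 8 and 6 fell without knockout replicate 3. DCN, the neighbour of LUM on chromosome 12, had 1 count in the controls and 38 in the knockouts, a ratio of 39.1 (95% counting interval 6.61 to 1585). ACOXL, next to BCL2L11 on chromosome 2, fell as well (log2 -3.17), but from few reads: 15, 14 and 11 in the controls and 1, 2 and 1 in the knockouts.

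Knockout replicate 3 stands apart from the other 2 knockout libraries. Transcript length is argued against, since after the GC correction its rank correlation with the difference was -0.053. GC content may contribute, since the rank correlation with the difference was -0.784, against -0.334 for replicate 1 minus replicate 2. After the GC correction the spread ratio fell from 2.79 to 1.52 (95% bootstrap interval 1.47 to 1.56). This interval lay wholly above the bound set beforehand for GC content as the whole cause, which argues against that cause. The interval crossed the bound of 1.5 set beforehand for rejecting that cause, so the planned test did not settle the question. Cells of another type stay open, since 1 of 61 markers of other cell types (CD3G) was at least 2-fold higher in that library than in both others. No biological explanation was tested, since the labels name no difference among these 3 libraries.

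Among the 12836 tested genes with a mean count of 10 or more, counts of 17 jump by at least 8-fold between replicates of a group, such as EEF1D with 19, 968 and 15 reads in the controls and 1037, 17 and 7 in the knockouts. Such genes lie in the MHC region of chromosome 6 (28 to 34 Mb) more often than others, 3 of 17 (odds ratio 41.9, 95% interval 7.55 to 156, Fisher's exact test p = 9.2e-05, two-sided). With the genes that the low-count filter drops, such as HLA-DPA1 (3, 7 and 410 reads in the controls), 10 of 33 lie there (odds ratio 85.0, 95% interval 34.7 to 195). This is consistent with reads shared with alternate copies of a locus in the reference, as a hypothesis. The edgeR adjusted p values of the 17 were 0.14 or higher, and no biological explanation was tested.

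Changed genes lie beside each other more often than chance order gives, with 248 adjacent pairs changed in the same direction against 83 to 149 in 1000 shuffles. GC content shared by neighbours is argued against, since after the GC correction, with 4849 changed genes, there were 1029 such pairs against 649 to 812 in shuffles. Of the 248 pairs 245 were among them, which adds no support, since 1926 of the 1941 calls were kept. A copy-number change of a segment is a candidate explanation for part of the pattern, since the window of chromosome 21 from 30 to 40 Mb had a median log2 fold change of -0.44 and -0.43 after the GC correction. Chromosomes 18 and 21 are not the whole cause, since the other chromosomes held 195 such pairs against 75 to 131 in shuffles. These others include chromosome 20, where most genes from 0 to 40 Mb were lower. The count therefore does not exclude copy-number changes beyond chromosomes 18 and 21. An effect of the SETD1B edit on neighbouring genes stays open as untested, and copy number was not measured.

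Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real split, gave as many changed genes, lists or pro-apoptotic members, and 10 splits are too few for a share under 0.05. The real split gave 1941 genes, 12 lists and 4 pro-apoptotic members. The highest of the other splits gave 0 genes by edgeR, 6 lists and 0 members. At an unadjusted p under 0.05 edgeR gave up to 915 genes in them, DESeq2 up to 1 at its adjusted threshold and limma-voom 0. Every other split mixed control and knockout libraries, so the difference between them widened the spread within its groups. Low numbers there are therefore likely whatever caused that difference, and they say nothing about its cause.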
